A study of Mus musculus with 2 samples.

How the data were processed

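H3K4me2 ChIP-seq peaks were analysed from limb tissue of B6NCrl mouse embryos at embryonic day 15.5, in 1 group of 2 biological replicates, pools of 78 and 62 embryos of mixed sex. No raw reads were processed. The authors deposited 4 peak lists in mm10 coordinates. These were a list for each replicate, a pooled list called on the alignments of both replicates, and a replicated list derived from the other 3. Per the labels, 2 further files whose role is not named entered all calls, and a control experiment is listed as possible. The aligner, the peak caller, its filters and the read depth were not given in the sources used here. In the deposited lists column 7 was read as the peak's fold enrichment, a ratio, and what it is relative to was not stated. In the deposited lists column 9 was read as the −log10 of the q-value, and column 10 as the position of the summit in bases from the peak's start. Both scores were used as the authors deposited them and ranked only within a list. No list held a peak past the end of a mm10 chromosome, and no list held overlapping peaks.

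Genes came from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and promoter sequence from its genome FASTA. Peaks on chromosomes 1 to 19, X and Y were used, and those on the mitochondrial genome and unplaced scaffolds were counted apart. Overlap meant at least 1 bp in common. Shuffles moved each peak at random within its chromosome 20 times with bedtools 2.31.1. A promoter was the window of 1 kb either side of the 5′ end of a protein-coding gene, and it was marked when a replicated peak overlapped it. Peak location was that of the midpoint, with promoter before exon, intron and intergenic space. Domains were replicated peaks merged when at most 1 kb apart, and a gene without a domain over its 5′ end counted as 0 bp. Distal peaks had a midpoint more than 1 kb from the 5′ end of any protein-coding gene. They were counted when that midpoint lay within 100 kb of a gene's 5′ end. Other annotated transcript starts were not considered for them. A gene whose 5′ end lay within 1 kb of another protein-coding 5′ end was said to share its promoter. CpG observed over expected was computed in 500 bp either side of the 5′ end.

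Before the data were examined 22 gene lists were fixed, of which 12 held genes of tissues present in the limb, 8 genes of other tissues and 2 reference genes (housekeeping and Hox genes). Every symbol was matched except Atp5f1b, whose older symbol Atp5b was also on the list, so the housekeeping list held 21 genes. Sox17 was on both the endothelium and the endoderm lists. Genes named in the text were chosen by a rule fixed at the same time. The rule took the 20 genes in the longest domains, and from each list up to 4 members with the longest domain over the 5′ end. It added up to 3 members without a domain for lists of limb tissues, in alphabetical order, and the HoxA and HoxD genes as groups. Tbx4, Pitx1, Apoa1, Nphs1, the unmarked Hox genes and the genes under the other observations were named outside the rule after their values were seen.

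Shares carry 95% Wilson intervals. Marked promoters of a list were compared with all other protein-coding genes by a two-sided Fisher's exact test. Domain lengths were compared by a two-sided permutation test of the list's median against 100000 random lists of the same size. Distal peaks were compared by a two-sided permutation test against 10000 random lists matched on quintiles of the number of protein-coding 5′ ends within 100 kb. Each family of 22 tests was adjusted by the Benjamini-Hochberg method, and an adjusted p of 0.05 was the threshold. Limb and other-tissue classes were compared with each other by Fisher's exact test and by a permutation test with 100000 resamples. Genes and peaks are not replicates, so these tests describe the lists of this tissue and not variation between animals. No test between samples was made with 2 replicates in 1 group.

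The alternatives tried were other promoter windows (0.5 and 2.5 kb), stricter q-values (0.01 and 1e-05), the 20000 best peaks of each list, overlap of 50% of either or both peaks, the pooled list, each replicate's own list alone, any annotated transcript start, CpG-matched lists (deciles), marked promoters only, no merging or merging within 3 kb, and a 50 kb distal window. Leaving out the Hox genes, leaving Hoxb13 out of the HoxB span and counting 1 gene per domain were added after seeing the data. The tests were tested on simulated data of 20000 genes with lists of 20. Lists built to differ had 95% of genes marked against 60% in the background, and longer domains. They were recovered in 96% of runs by Fisher's exact test, 99% by the permutation of the median, 94% by the matched permutation and 98% by the difference of medians. Lists without a difference had an unadjusted p below the threshold in 7%, 0%, 4% and 6% of runs. The simulated genes were independent and their strata were unrelated to marking, so these rates need not hold for real lists with smaller differences, shared domains or unequal CpG content. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with a fixed seed.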

Results

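H3K4me2, a histone modification found at promoters and enhancers, was mapped by ChIP-seq in whole limb tissue of B6NCrl mouse embryos at embryonic day 15.5. The series held 1 group with 2 biological replicates. Replicate 1 was a pool of limbs from 78 embryos of both sexes and replicate 2 a pool from 62. Replicate 1 had 50040 H3K4me2 peaks with a median width of 504 bp, and replicate 2 had 46418 with a median width of 575 bp. The peaks covered 43.9 Mb in replicate 1 and 43.6 Mb in replicate 2, which was 1.61% and 1.60% of the chromosomes. A list called on the pooled alignments held 47074 peaks, and a list of replicated peaks held 34411. Read depth was not given in the sources used here, so confidence intervals cover counting error of peaks or genes only. Coordinates refer to mm10 and are counted from 1, and fold enrichment is the authors' own score, ranked only within a list.

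The first comparison asked how far the peaks of one pool of limbs were found in the other. In replicate 1, 36363 of 50015 peaks on the assembled chromosomes overlapped a peak of replicate 2, a share of 72.7% (95% Wilson interval 72.3 to 73.1). In replicate 2, 35538 of 46402 peaks overlapped a peak of replicate 1, a share of 76.6% (76.2 to 77.0). Peaks placed at random within their chromosomes overlapped in 3.43% and 3.68% of cases, with a range over 20 shuffles of 3.29 to 3.62% and 3.58 to 3.85%. The replicates shared 37.0 Mb, which was 73.3% of the bases covered in either. Strong peaks were shared and weak peaks often were not. In the lowest quintile of fold enrichment 27.2% of replicate 1's peaks and 33.6% of replicate 2's peaks were found in the other replicate. The shares were 87.8% and 93.7% in the middle quintile and rounded to 100% in the highest quintile of each list.

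Peaks found in 1 replicate alone were short, weak and seldom near promoters. The 13652 peaks of replicate 1 without a partner had a median width of 224 bp and a median fold enrichment of 2.88, against 844 bp and 8.91 for its shared peaks. Of these 13652 peaks, 4.09% lay within 1 kb of the 5′ end of a protein-coding gene, against 38.9% of the shared peaks. Replicate 2 gave like values, with 10864 peaks without a partner, a median width of 229 bp against 871 bp, and 4.35% near a 5′ end against 39.0%. With 2 samples in 1 group no test between samples could be made. A demand that the overlap reach 50% of both peaks gave the lowest shares, at 57.9% for replicate 1 and 62.4% for replicate 2.

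**Figure D1:**
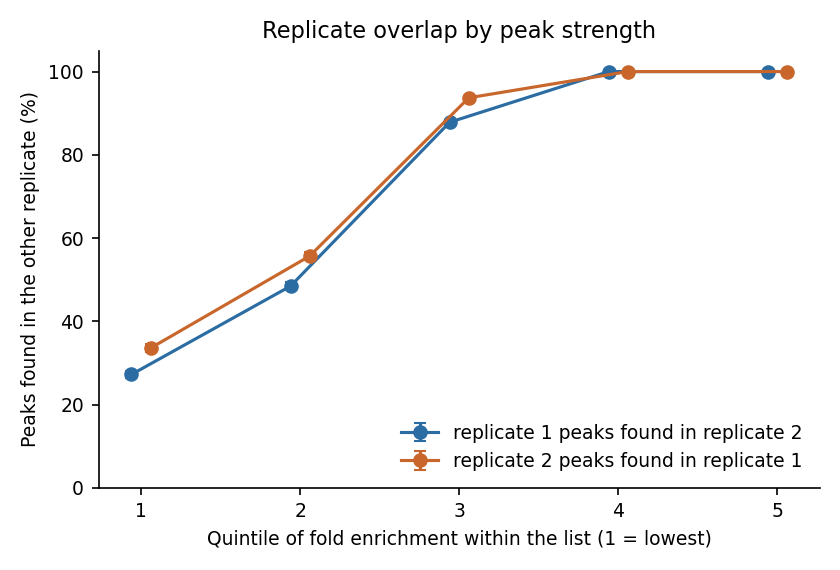
The share of peaks found in the other replicate (vertical axis, %) is plotted by quintile of fold enrichment within each replicate's own list (horizontal axis), with 95% Wilson intervals as error bars. The share is 27.2% for replicate 1 and 33.6% for replicate 2 in the lowest quintile and rounds to 100% for both in the highest.

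The replicated list held the wide and strong part of the pooled list. Of 47052 pooled peaks on the assembled chromosomes, 34394 were kept, a share of 73.1% that carried 93.0% of the pooled bases. Kept peaks had a median width of 995 bp and a median fold enrichment of 10.2, against 236 bp and 2.61 for the 12658 peaks not kept. Every one of the 32333 pooled peaks that overlapped a peak of each replicate by 50% of either peak was kept. The other 2061 kept peaks, 5.99% of the replicated list, did not meet that overlap in the deposited lists. Of the replicated peaks, 97.3% overlapped a peak of replicate 1 and 96.8% a peak of replicate 2. The comparisons that follow used the 34394 replicated peaks on chromosomes 1 to 19, X and Y.

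H3K4me2 in the limb was concentrated at promoters, although most peaks lay elsewhere. The midpoints of 13014 peaks, 37.8% (95% Wilson interval 37.3 to 38.4), lay within 1 kb of the 5′ end of a protein-coding gene. Shuffled peaks gave 1.69%, so promoters held 22.4 times the shuffled share. Exons held 8.68% of midpoints against 3.56% in shuffles, a ratio of 2.44. Introns held 27.1% against 37.1%, a ratio of 0.731, and intergenic space held 26.4% against 57.7%, a ratio of 0.457. The 14971 peaks that reached into a promoter window were wider than the 19423 that did not, with medians of 1723 bp and 640 bp. The median fold enrichment was 18.7 for peaks that reached into a window, against 4.76 for the others. A two-sided permutation test over peaks gave p = 1e-05 for both differences, the smallest it can give, and peaks are not replicates. The promoter share depended on the window and was 23.8% with 0.5 kb either side.

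**Figure D2:**
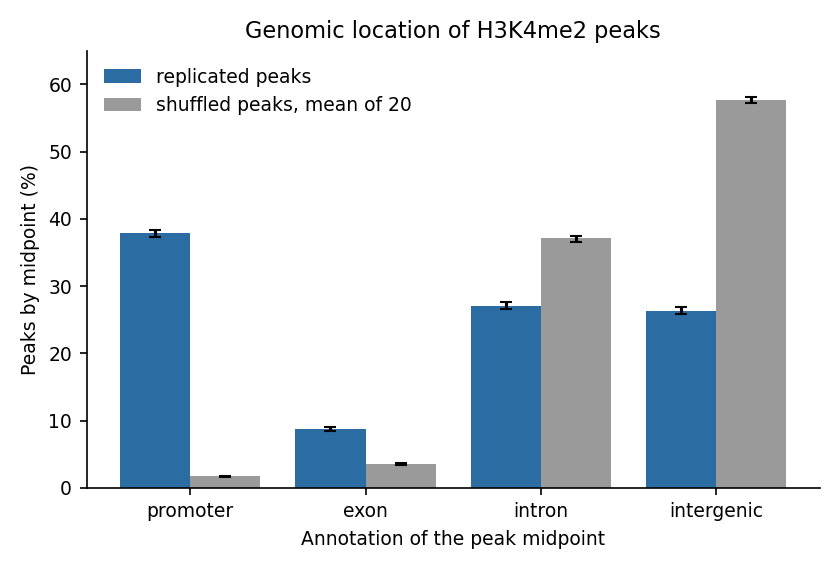
Bars give the share of replicated peak midpoints (vertical axis, %) in promoters, exons, introns and intergenic space with 95% Wilson intervals, and grey bars the mean of 20 within-chromosome shuffles with their lowest and highest value. Promoters hold 37.8% of peaks against 1.69% in shuffles, and intergenic space holds 26.4% against 57.7%.

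Of 21938 protein-coding genes, 14057 had a marked promoter, meaning a replicated peak within 1 kb of the gene's 5′ end, a share of 64.1% (95% Wilson interval 63.4 to 64.7). The next comparison asked how often promoters of genes of limb tissues and of other tissues were marked, through 22 gene lists. Expression was not measured, so a marked promoter does not show that its gene was active. All 34 limb patterning transcription factors were marked, among them Tbx5 and Tbx4, regulators of forelimb and hindlimb outgrowth, Pitx1, a hindlimb identity factor, and Lmx1b, which specifies dorsal limb pattern. All 12 cartilage regulators were marked, including Sox9, the chondrocyte master regulator, and Trps1. Of 20 tendon and joint genes 18 were marked, among them Osr2, Scx, a tendon progenitor factor, and Mkx. At the other end, 2 of 25 liver effector genes (Apoa1 and Apoh) and 3 of 25 gut, lung, kidney and pancreas effector genes (Lgr5, Nphs1 and Nphs2) were marked. Among 1464 olfactory and vomeronasal receptors 4 were marked (Vmn1r4, Olfr1342, Olfr1033 and Olfr658).

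Two-sided Fisher's exact tests against all other protein-coding genes, adjusted over the 22 lists, placed 7 lists above the background and 6 below. Limb patterning transcription factors stood at 100% against 64.0% (exact p = 5.32e-07, adjusted p = 2.92e-06) and cartilage regulators at 100% against 64.1% (exact p = 0.00585, adjusted p = 0.0161). Tendon and joint genes stood at 90.0% (exact p = 0.0175, adjusted p = 0.0299), limb signalling genes at 87.5% with 21 of 24 marked (exact p = 0.0177, adjusted p = 0.0299) and Hox genes at 89.7% with 35 of 39 (exact p = 6.03e-04, adjusted p = 0.00265). The remaining pair above were housekeeping genes at 95.2% with 20 of 21 (exact p = 0.00211, adjusted p = 0.00773) and central nervous system transcription factors at 86.7% with 26 of 30 (exact p = 0.0118, adjusted p = 0.0236). Below the background were liver effector genes at 8% (exact p = 7.53e-09, adjusted p = 8.28e-08), gut, lung, kidney and pancreas effector genes at 12% (exact p = 1.06e-07, adjusted p = 7.77e-07) and olfactory and vomeronasal receptors at 0.273%. Germ line and pluripotency genes (7 of 21, exact p = 0.00517, adjusted p = 0.0161), muscle contractile genes (9 of 24, exact p = 0.00953, adjusted p = 0.0210) and blood and osteoclast genes (7 of 20, exact p = 0.00937, adjusted p = 0.0210) were also below.

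The other 9 lists did not pass the test. Marked were 17 of 22 epidermis genes, 11 of 15 muscle regulators, 14 of 20 cartilage matrix genes, 12 of 19 endothelium genes, 9 of 14 Schwann cell and melanocyte genes and 8 of 18 bone genes. Among lists of other tissues, 15 of 21 endoderm and kidney transcription factors, 19 of 27 neuron effector genes and 8 of 17 heart genes were marked. Against random lists matched on promoter CpG content no list stood above and 2 stood below, the olfactory receptors and the germ line genes, and limb patterning transcription factors had an adjusted permutation p of 0.192. The unadjusted permutation p was 0.0252 for tendon and joint genes, 0.0312 for cartilage matrix genes and 0.0438 for cartilage regulators, all above their matched lists. Muscle contractile genes and blood and osteoclast genes then stood 0.429 and 0.876 points above their matched lists and central nervous system transcription factors −1.60 points from theirs, the reverse of the directions against all genes. From a single replicate's peaks the exact test no longer passed for cartilage regulators or central nervous system transcription factors with either replicate (adjusted p 0.0595 to 0.106), nor for muscle contractile or blood and osteoclast genes without replicate 1 (adjusted p = 0.0638 for both). Another promoter window or any annotated start ended the call for limb signalling, tendon and joint, central nervous system, germ line, muscle contractile or blood and osteoclast genes (adjusted exact p 0.0571 to 0.386), as did q at most 1e-05 for cartilage regulators (adjusted exact p = 0.677), while muscle regulators passed without replicate 2 (28.5 points above, adjusted exact p = 0.0487) and with the pooled list (0.0418), and heart genes with a 0.5 kb window (0.0425).

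**Figure D3:**
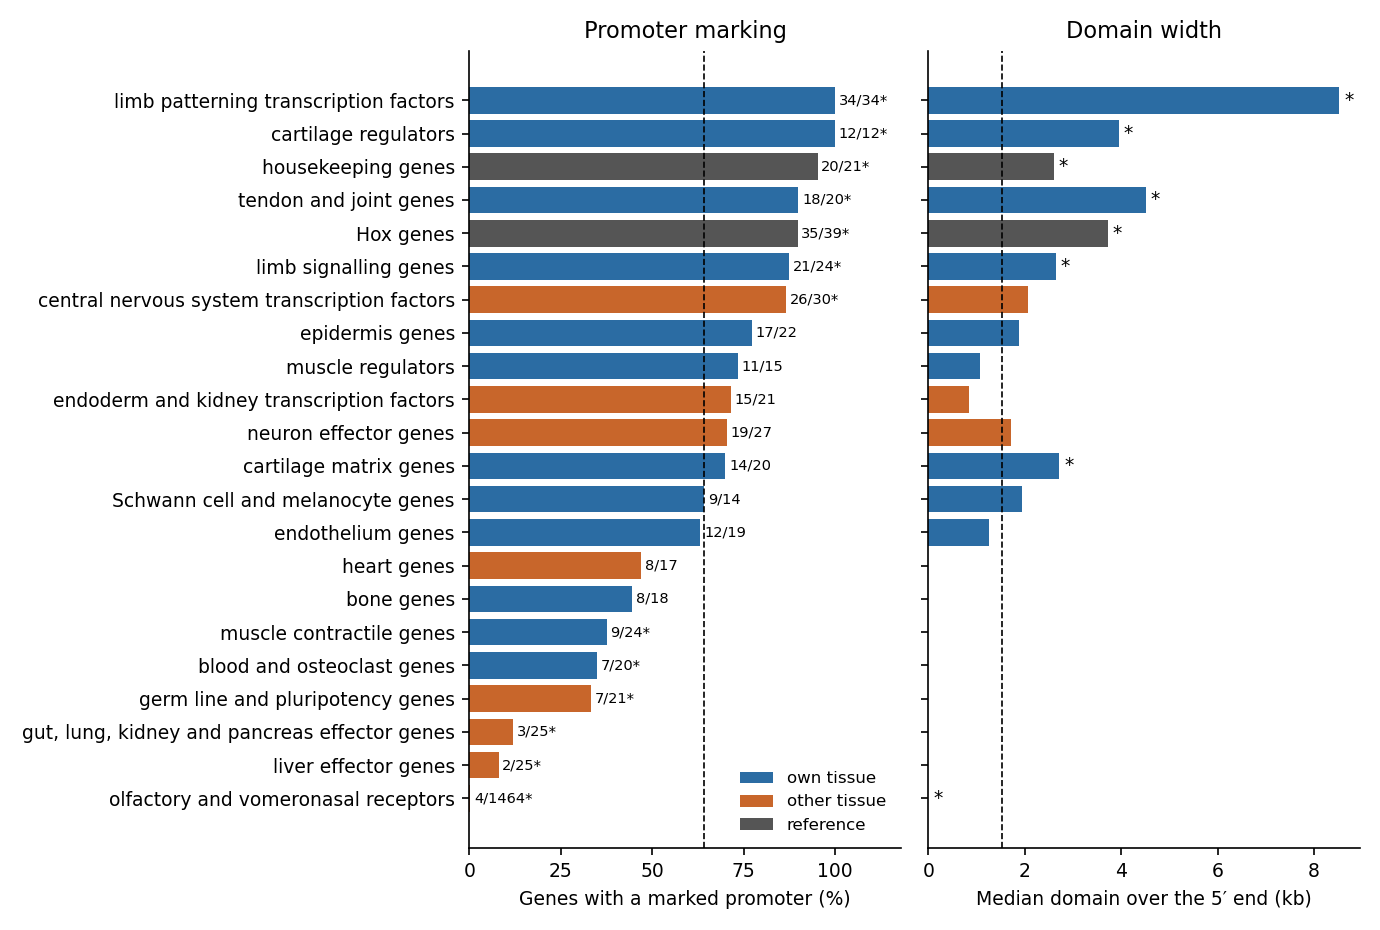
Bars give the share of each list's genes with a marked promoter (%), with the count of marked genes beside each bar, an asterisk where the adjusted exact p is below 0.05 and a dashed line at 64.1% for all protein-coding genes. Limb patterning transcription factors and cartilage regulators reach 100%, and olfactory and vomeronasal receptors 0.273%.

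Wide H3K4me2 domains lay over limb developmental genes. Replicated peaks at most 1 kb apart were merged into 28242 domains with a median length of 1290 bp, and 13276 genes had a domain over the 5′ end. Limb patterning transcription factors had a median domain of 8525.5 bp, against 1522 bp for all protein-coding genes. The domain was 16469 bp at Tbx5 (5:119829519–119845987), 16911 bp at Lmx1b (2:33629919–33646829), 15939 bp at Tbx2, 6425 bp at Tbx4 and 3355 bp at Pitx1. Prrx2 and Sall4, of the same list, had a marked promoter but no domain over the 5′ end. Tendon and joint genes had a median of 4509 bp, led by Osr2 (10149 bp), Scx (9825 bp), the tendon and ligament collagen Col12a1 (7055 bp) and Mkx (6315 bp), while Prg4, which encodes lubricin, and the tendon gene Tnmd had no domain.

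Cartilage genes also carried wide domains. Cartilage regulators had a median of 3957.5 bp, with 11300 bp at Sox6, which shared its promoter with a neighbour, 10029 bp at Foxc1, 8651 bp at Sox9 (11:112779671–112788321) and 8505 bp at Trps1. Runx3 and Mef2c had no domain over the 5′ end, and the promoter of Mef2c was not marked in replicate 2. Cartilage matrix genes had a median of 2715 bp, with 6251 bp at Col2a1, the main cartilage collagen, 5680 bp at Acan, which encodes aggrecan, 5240 bp at Matn4 and 4929 bp at Col9a3. Col10a1, a marker of hypertrophic chondrocytes, Col9a1 and Cytl1 had no domain, although another annotated start of Col9a1 was marked. Limb signalling genes had a median of 2642 bp, with 22009 bp at Ptch1, the hedgehog receptor (13:63552596–63574604), 14757 bp at Wnt5a, 8008 bp at Bmp7 and 7150 bp at Fgf9. Fgf10, Fgf4 and Cyp26b1 had no domain at the gene's 5′ end, but each had another annotated start that was marked.

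In a two-sided permutation test against random lists of the same size, 7 lists had wider domains than all genes after adjustment over 22 lists. Limb patterning transcription factors, tendon and joint genes and Hox genes (median 3730 bp) each had a permutation p of 2e-05, the smallest it can give, and an adjusted p of 1.1e-04, although with 1 gene counted per domain, chosen after seeing the data, the Hox list exceeded random lists by 726 bp and not 2208 bp (unadjusted permutation p = 0.0352). The permutation p was 6e-05 for cartilage regulators (adjusted p = 2.64e-04), 0.00226 for limb signalling genes (adjusted p = 0.00829), 0.00272 for cartilage matrix genes (adjusted p = 0.00855) and 0.0057 for housekeeping genes with a median of 2599 bp (adjusted p = 0.0157). Olfactory and vomeronasal receptors were below, with a median of 0 bp. Central nervous system transcription factors did not pass, with a median of 2062.5 bp (permutation p = 0.118, adjusted p = 0.287). The other lists that did not pass had medians of 1934.5 bp for Schwann cell and melanocyte genes, 1888.5 bp for epidermis genes, 1716 bp for neuron effector genes, 1252 bp for endothelium genes, 1061 bp for muscle regulators and 836 bp for endoderm and kidney transcription factors. The call for housekeeping genes was lost against CpG-matched lists (adjusted permutation p = 0.232), among marked promoters only (0.255) and without merging (0.976), that for olfactory receptors against CpG-matched lists (adjusted permutation p = 1), and that for cartilage matrix genes without replicate 2 (list minus random 792 bp, adjusted permutation p = 0.162). Central nervous system transcription factors passed with any annotated start (adjusted permutation p = 0.0124), epidermis genes with merging within 3 kb (0.0230), and against CpG-matched lists Schwann cell and melanocyte genes were above (0.0181) and endoderm and kidney transcription factors below (0.00754). With medians of 0 bp, the lists of bone, muscle contractile, blood and osteoclast, liver, gut, heart and germ line genes had little room to pass.

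Single genes of the remaining limb tissues had wide domains even where their list did not pass. Among bone genes, Col1a1, the main bone collagen, had a domain of 14839 bp (11:94932813–94947651) and Col1a2 of 7534 bp, followed by Bmp3 (3816 bp) and Dlx3 (3147 bp), while Bglap, Dmp1 and Ibsp had none. Among muscle regulators, Lbx1, needed for muscle precursor migration into the limb, had 7810 bp, Six4 3866 bp, Six1 2615 bp and Met 2573 bp. Myf5, Myf6 and Mymk had no domain, and the promoter of Myf6 was marked, while that of Mymk had a peak in each replicate's own list but none in the replicated list. Of the muscle contractile genes, Mylpf (4571 bp), Myl4 (2449 bp) and Ckm (2431 bp) shared promoters with neighbours, Des had 1837 bp, and Acta1, Actc1 and Chrna1 had none. The epidermal regulators Tfap2a (11931 bp), Grhl3 (7339 bp), Klf4 (6305 bp) and Tfap2c (4930 bp) led their list, in which Dsg3, Ivl and Krt1 had no domain over the 5′ end and another start of Krt1 was marked.

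Vascular, blood and glial genes showed the same mix. Fli1 (6656 bp), Erg (5141 bp), Prox1, the lymphatic regulator (5027 bp), and Sox18 (2249 bp) led the endothelium list, in which Cdh5, Egfl7 and Emcn had no domain at the 5′ end and another start of Egfl7 was marked. Nfatc1, an osteoclast regulator (9095 bp), Epor (2236 bp), Ctsk (2035 bp) and Tal1 (1814 bp) led the blood and osteoclast list, in which Acp5, Alas2 and Cd68 had none and another start of Acp5 was marked. Egr2 (4396 bp), Erbb3 (4216 bp), Ngfr (3339 bp) and S100b (2582 bp) led the Schwann cell and melanocyte list, in which Dct, Mlana and Plp1 had none. Among genes of other tissues, the widest domains lay at Bcl11b (9864 bp), Emx2 (9701 bp), Dlx2 (7402 bp) and Otx1 (4960 bp) for the central nervous system and at Six2 (7442 bp), Foxa3 (5026 bp, shared promoter), Gata6 (3565 bp) and Nkx6-1 (3009 bp) for endoderm and kidney. Neuron effector genes were led by Gria2 (3097 bp), Nefm (2785 bp), Slc17a7 (2557 bp) and Slc18a3 (2269 bp), and heart genes by Irx4 (5701 bp), Hcn4 (3094 bp), Ryr2 (1964 bp) and Gja5 (1702 bp, shared promoter). Lgr5 had 3228 bp and Nphs2 611 bp, Apoh 3056 bp at a shared promoter, and Gdf9 2322 bp at a shared promoter, with Utf1 at 1211 bp and Ddx4 at 490 bp. Housekeeping genes were led by Rpl13a (7105 bp), Polr2a (5127 bp), Tbp (4711 bp, shared promoter) and Pgk1 (4351 bp), and receptors by Vmn1r4 (2180 bp, shared promoter), with 401 bp at Olfr1342, 321 bp at Olfr1033 and 260 bp at Olfr658.

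Distal H3K4me2 peaks were more numerous around the genes of 10 lists than around genes of like local density. Their midpoints lay more than 1 kb from any protein-coding gene's 5′ end. Wide peaks over a 5′ end could count among them, as did the HoxD peak of 15316 bp over the 5′ ends of Hoxd11 and Hoxd12. Other annotated starts of a gene were not treated as promoters. How far either point raised the counts was not tested. Limb patterning transcription factors had 12.5 ± 8.31 distal peaks within 100 kb of the 5′ end (mean and SD across 34 genes), against 2.83 for random lists matched on local gene density. Their HoxA and HoxD members count the same cluster peaks repeatedly, and without them, a choice made after seeing the data, the other 25 genes had 8.52 against 2.12 (permutation p = 2e-04, the smallest it can give). Hox genes had 22.1 ± 3.29 against 4.77, where peaks inside the clusters are counted for several genes at once. Other lists also held neighbours whose windows overlapped, such as the muscle contractile genes Chrng and Chrnd with 9 and 10 distal peaks. The random lists were not matched on such neighbours, and the effect of peaks counted repeatedly outside the Hox clusters was not tested. Bone genes had 5.89 ± 4.50 against 2.84, cartilage regulators 5.75 ± 3.22 against 2.45, muscle contractile genes 5.58 ± 4.99 against 3.17 and cartilage matrix genes 4.85 ± 3.36 against 2.84. Central nervous system transcription factors had 5.63 ± 3.40 against 2.12, and endoderm and kidney transcription factors 4.76 ± 3.63 against 2.40. Limb signalling genes had 4.29 ± 2.93 against 2.38 and endothelium genes 4.84 ± 3.62 against 2.86.

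These 10 lists passed the two-sided permutation test after adjustment over 22 lists. The permutation p was 2e-04, the smallest it can give, for limb patterning transcription factors, Hox genes and central nervous system transcription factors (adjusted p = 0.0011 for each). Bone genes had an adjusted permutation p of 0.00264, endoderm and kidney transcription factors 0.0066, cartilage regulators 0.0107, muscle contractile genes 0.0110, limb signalling genes 0.0127, cartilage matrix genes 0.0255 and endothelium genes 0.0416. Olfactory and vomeronasal receptors were below, at 0.275 ± 0.963 peaks against 3.77, with the same smallest permutation p. Tendon and joint genes, muscle regulators and housekeeping genes missed the threshold, each with an adjusted permutation p of 0.0767. The calls for cartilage matrix and endothelium genes were lost with peaks of q at most 1e-05 (adjusted permutation p 0.0874 and 0.0734), and that for endothelium genes also with a 50 kb window (0.0691). Without replicate 2, muscle regulators (adjusted permutation p = 0.0440), housekeeping genes (0.0264) and, below their background, liver effector genes (0.0440) also passed, as tendon and joint genes did without replicate 1 (0.0444) and with a 50 kb window (0.0101).

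The difference between limb and other tissues was then tested directly. Among transcription factors, 34 of 34 limb patterning genes were marked against 41 of 51 of the central nervous system, endoderm and kidney (80.4%), with a two-sided Fisher's exact p of 0.00498. The comparisons between classes were not matched on CpG content. Random lists matched on promoter CpG content were marked in 93.4% of cases for the limb factors and 83.5% for the others, so part of the difference in marking went with CpG content. The median domain of the limb factors was 8525.5 bp against 1429 bp, with a two-sided permutation p of 1e-05, the smallest it can give. Without the Hox genes, a choice made after seeing the data, the remaining 25 limb patterning factors had a median domain of 7324 bp against 1429 bp (permutation p = 1e-05). Among effector genes, 23 of 44 cartilage matrix and muscle contractile genes (52.3%) were marked against 24 of 77 of neurons, liver and gut, lung, kidney and pancreas (31.2%), with a Fisher's exact p of 0.0324. The member lists were unlike, since cartilage matrix genes (70.0%) stood near neuron effector genes (70.4%) and muscle contractile genes at 37.5%, so the pooled difference rested on the low shares of liver and of gut, lung, kidney and pancreas genes. The median domain was 0 bp in both effector groups. The exact test of marked promoters lost its call for transcription factors with a 2.5 kb window or with any annotated start (exact p = 0.0767 for both), and for effector genes with a 0.5 kb window (exact p = 0.0763). With any annotated start the median domain of limb effector genes was 560 bp longer than that of the others (permutation p = 0.0159).

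**Figure D4:**
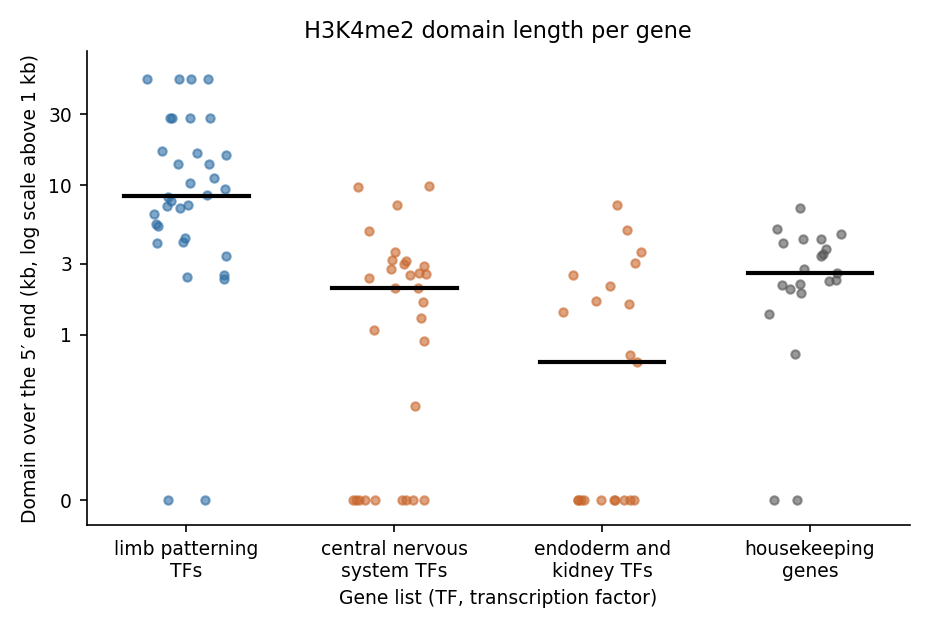
Each point is the length of the H3K4me2 domain over the 5′ end of 1 gene (vertical axis, linear below 1 kb and logarithmic above), and the line is the median of the list. Housekeeping genes are shown beside the lists of transcription factors. Limb patterning factors have a median of 8525.5 bp, central nervous system factors of 2062.5 bp and endoderm and kidney factors of 836 bp.

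Several of the widest domains held developmental regulators of the limb. The longest, 51705 bp and 13 peaks, spanned Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 (6:52215257–52266961), and a domain of 28511 bp spanned Hoxd10, Hoxd11, Hoxd12 and Hoxd13 (2:74666015–74694525). Among domains over a protein-coding 5′ end, these were followed by Ptch1 (22009 bp), Ebf3 (17374 bp), Lmx1b, Tbx5, Bahcc1 (16113 bp), Tbx2, Col1a1, Wnt5a and Zfp503 (14610 bp). A domain of 14396 bp held the 5′ ends of Maz and Gm42742, the latter a shared promoter. Of the 500 longest domains, each at least 5660 bp, 44 (8.80%) held the 5′ end of a gene from the own-tissue lists, against 103 of 27742 others (0.371%, Fisher's exact p = 1.54e-41). Among domains with any protein-coding 5′ end the counts were 44 of 412 and 103 of 11437 (Fisher's exact p = 1.74e-29). Without merging of peaks the share was 5.6%.

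The Hox clusters, of which HoxA and HoxD pattern the limb along its proximal to distal axis, were covered unequally. Replicated peaks covered 61.8% of HoxA (6:52155590–52260880) and 46.2% of HoxD (2:74668310–74765142), against 29.0% of HoxC and 15.3% of HoxB. The order was the same in each replicate, with 58.8% and 59.2% for HoxA, 41.2% and 45.0% for HoxD, 27.6% and 25.7% for HoxC and 14.6% and 13.4% for HoxB in replicates 1 and 2. The low share of HoxB rested in part on the long interval between Hoxb13 and Hoxb9, and with Hoxb13 left out, a choice made after seeing the data, 23.9% of the remaining 96800 bp was covered (22.7% in replicate 1 and 20.3% in replicate 2). The longest replicated peak of the 4 clusters, 15316 bp, lay in HoxD, whereas in each replicate's own list the longest lay in HoxA (8085 bp in replicate 1 and 8436 bp in replicate 2). The genes of groups 9 to 13 had a median domain of 51705 bp in HoxA and 28511 bp in HoxD, against 2482 bp in HoxC and 1499.5 bp in HoxB. In groups 1 to 8 the medians were 3730 bp in HoxA, 4353.5 bp in HoxD, 2812 bp in HoxC and 0 bp in HoxB. All 11 HoxA and all 9 HoxD genes had a marked promoter, as did 8 of 9 HoxC and 7 of 10 HoxB genes. The unmarked genes were Hoxb2, Hoxb3, Hoxb8 and Hoxc4, each of which had another annotated start that was marked, so that with any annotated start all 39 Hox genes were marked. Neighbouring Hox genes shared domains and were not independent, and with 1 gene counted per domain the Hox list had a median of 2247 bp.

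**Figure D5:**
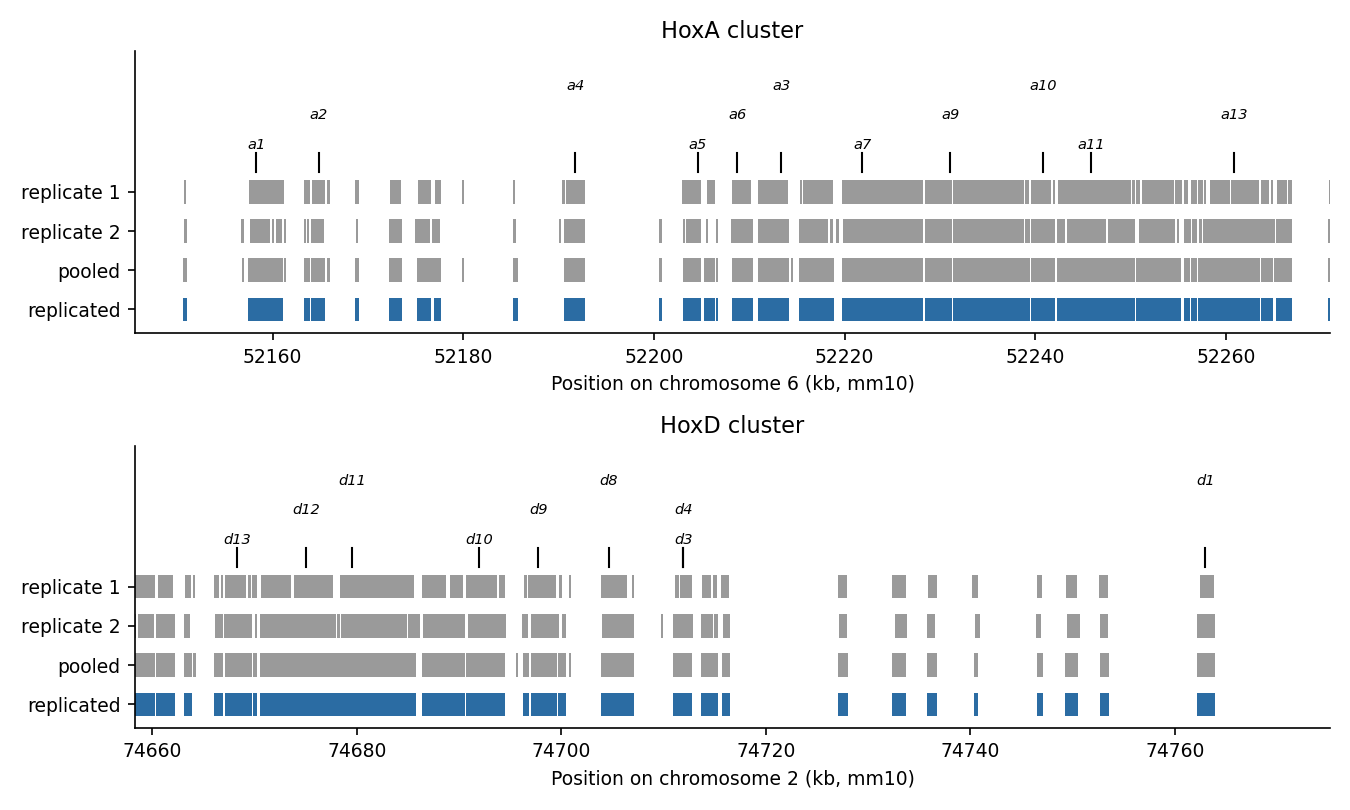
The panels map the HoxA and HoxD clusters in mm10 (horizontal axis, position along the chromosome), with ticks at the gene 5′ ends and boxes for the peaks of the replicate, pooled and replicated lists. Replicated peaks cover 61.8% of HoxA and 46.2% of HoxD.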

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

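The tests of gut, lung, kidney or pancreas cells and of CpG content alone were chosen after the result was seen.

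Peaks outside the assembled nuclear chromosomes took no part in the comparisons. The mitochondrial genome held 11 peaks in replicate 1's list, 1 in replicate 2's, 5 in the pooled list and 3 in the replicated list. Unplaced scaffolds held 14 peaks in replicate 1's list, 15 in replicate 2's, 17 in the pooled list and 14 in the replicated list. No expected count was available, so these counts were not tested. No explanation was tested for the peaks of the mitochondrial genome or of the scaffolds.

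Transcription factors of the central nervous system, endoderm and kidney were marked in limb in 41 of 51 cases (80.4%). Cells of those tissues in the dissected limb were predicted beforehand to leave their effector genes marked as often as genes of like CpG content. A small share of such cells need not raise the effector genes that far, so a shortfall could not exclude them. These effector genes were marked in 31.2% of cases against 41.0%, a difference of −9.79 percentage points (permutation p = 0.0112). That is just inside the bound of 10 points set beforehand, so such cells stay open for the whole class, in which neuron effector genes (70.4%) did not lie below their CpG-matched lists (70.5%). For the endoderm and kidney factors alone, gut, lung, kidney or pancreas cells stay open too, since their effector genes lay at 12% against 28.5%, a difference of −16.5 points (permutation p = 0.0178), but did not pass when all 22 lists were compared with CpG-matched lists (adjusted permutation p = 0.137). A candidate explanation that also remains is CpG-rich promoters, since the 51 factors differed by −3.11 points from CpG-matched lists (83.5%, range of 95% of lists 76.5 to 90.2, permutation p = 0.493), and true use of some of these factors in limb cells was not tested.

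At 1164 of 14057 marked genes (8.28%) the 5′ end itself was uncovered between a pair of flanking peaks, with a median gap of 179 bp, while 12120 genes (86.2%) had the 5′ end covered. Genes whose transcript starts all lie within 200 bp showed the gap 0.800 times as often as other genes (95% interval 0.699 to 0.915, 6.98% against 8.73%, Fisher's exact p = 9.57e-04). These values argue against spread among a gene's annotated starts as the only source of the gaps, although the lower share leaves it room as a part. Misplaced annotated 5′ ends stay open, because that class includes genes with a single annotated start, and starts that lie close together can be misplaced together. Whether CpG content of the promoter alone accounts for the gaps stays open, since a comparison of 108 marked developmental regulators with CpG-matched marked genes (0 against 7.55%, a difference of −7.55 points) used a set put together after the gaps were seen, without the lists that hold Hoxb7 and Hand1, and so decides nothing. Weak signal split by the peak caller stays open. The mean fold enrichment of each flanking pair had a median of 14.6, against 20.6 for peaks over covered ends, a difference of −6.07 (permutation p = 1e-05, the smallest it can give). This cannot decide it, since a mean over a pair was set against a single peak's score, which can lower the flanking value whatever the cause. CpG-rich promoters may contribute, with 13% of CpG-rich against 3.51% of CpG-poor genes, a difference of 9.53 points (Fisher's exact p = 9.87e-99). Some neighbouring genes, such as Bag4 and Lsm1, shared the same gap, so the genes in this test were not independent. No biological explanation, such as loss of nucleosomes at highly transcribed starts, was tested, and the design held no group that could test one.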

How the results depend on the processing

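Leaving out the Hox genes or Hoxb13 and counting 1 gene per domain were chosen after seeing the data. No paired analysis was possible because the series held a single group. Among the values that answer a comparison, 79 alternatives left direction, threshold or value as reported, 40 moved a value beyond its spread or counting interval or a count beyond 1.5 times, 3 lost a call and 1 gained one. Among single lists, 441 kept direction and side of the threshold, 32 lost a call, 12 gained one and 3 reversed. Depth was not given, so its effect could not be examined. Except where the setting's own construction decides (window size, stricter overlap, fewer peaks), the cause was not tested.

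The share of peaks found in the other replicate was, for replicate 1 and replicate 2, 69.3% and 73.1% with 50% of either peak, 57.9% and 62.4% with 50% of both, 81.2% and 79.6% at q at most 0.01, 91.6% and 92.3% at q at most 1e-05, and 96.9% and 95.85% for the 20000 best peaks. Pooled peaks were kept in 79.4% of cases at q at most 0.01 and 97.3% at 1e-05. With a 0.5 kb window promoters, exons, introns and intergenic space held 23.8%, 12.5%, 35.3% and 28.4% of peaks, and with 2.5 kb 47.2%, 6.27%, 21.3% and 25.2%. Marked promoters came to 63.0% with 0.5 kb, 65.9% with 2.5 kb, 65.1% with the pooled list, 67.6% with any annotated start, and 64.6% to 64.8% from a single replicate.

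Against CpG-matched lists 0 lists were above and 2 below the background. There muscle contractile genes (0.429 points), blood and osteoclast genes (0.876 points) and central nervous system transcription factors (−1.60 points) reversed, with adjusted permutation p of 1 for each. From a single replicate 1 to 2 lists had fewer distal peaks, with 2 without replicate 2. Limb transcription factors exceeded the others by 11.8 points with 2.5 kb and with any annotated start (Fisher's exact p = 0.0767 for both), and limb effector genes by 17.9 points with 0.5 kb (Fisher's exact p = 0.0763). The domains of limb effector genes were 560 bp longer with any annotated start (permutation p = 0.0159). Without merging, 5.6% of the 500 longest domains held a limb list gene.

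HoxA was covered to 60.6% at q at most 1e-05, 63.2% in the pooled list and 58.8% to 59.2% in a single replicate. HoxC was covered to 27.1%, 31.6% and 25.7% to 27.6% in the same order. HoxB was covered to 16.9% in the pooled list, 23.9% with Hoxb13 left out and 13.4% to 14.6% in a single replicate, and HoxD to 41.2% to 45.0% in a single replicate.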

Other observations

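The observations and tests in this part were all chosen after the data were seen.

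Several limb regulators were marked at a start other than the gene's annotated 5′ end. Runx2, the osteoblast master regulator, was unmarked at its 5′ end but had a peak at 17:44733590–44738667 over a start 78621 bp away, with a fold enrichment of 30.4. Runx1 had such a peak at 16:92696471–92700416, over a start 128821 bp away, with a fold enrichment of 42.5. Fgf10, a limb outgrowth signal, had one 44908 bp away with a fold enrichment of 25.9, and Cyp26b1, a retinoic acid degrading enzyme, one 6228 bp away with a fold enrichment of 34.4. The keratin genes Krt1 and Krt10 had marked starts 4200 bp and 3267 bp away, with fold enrichments of 25.9 and 14.6. Of the 70 limb tissue list genes without a marked 5′ end, 14 (20.0%) had another start marked, against 10 of 86 (11.6%) on lists of other tissues without the olfactory and vomeronasal receptors, a difference that did not pass Fisher's exact test (p = 0.183).

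Long domains also lay away from the 5′ ends of protein-coding genes. Of 28242 domains, 15691 (55.6%) had no such end within 1 kb, and 83 of the 500 longest (16.6%) were of this kind. Other annotated transcript starts were not examined for these domains, so some of them may lie over another promoter of the same gene. The longest lay inside Tbx15, a limb and skeletal regulator (3:99248067–99265179, 17113 bp), and inside Nfib (4:82499143–82513953, 14811 bp). Others lay inside the retinoic acid receptor genes Rarg (15:102242671–102252972, 10302 bp) and Rara (11:98935912–98945812, 9901 bp). A domain of 9340 bp at 8:107544149–107553488, inside Wwp2, held the 5′ end of Mir140, a microRNA of cartilage. Domains of 9122 bp and 9055 bp held the 5′ ends of the non-coding RNAs Malat1 and Neat1.

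Among long non-coding RNA genes more than 1 kb from a protein-coding 5′ end, 1566 of 8723 (18.0%) were marked, against 1274 of 1427 (89.3%) of those nearer and 330 of 13410 pseudogenes (2.46%). The windows of the nearer genes overlap a protein-coding promoter, so a peak of that promoter can count for both genes. Their share therefore does not describe non-coding promoters by themselves. Hottip and Hoxa11os lay in the HoxA domain of 51705 bp, Hand2os1 lay in the domain over Hand2 (11242 bp) and Crnde in that over Irx5 (13832 bp). The highest counts of distal peaks within 100 kb were found around Lyl1 and G430095P16Rik on chromosome 8, with 35 each, and Nfix nearby had 30. Chromosome X held 5.39 replicated peaks per Mb, against 9.50 to 22.4 on the autosomes (median 14.0), and 49.2% of its protein-coding promoters were marked, against 52.9 to 77.4% on the autosomes.

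The uncovered 5′ ends described with the flanking peaks were found on 7 of 20 marked housekeeping genes (Actb, Hprt, Polr2a, Sdha, Pgk1, Rpl13a and Atp5b), a share of 35.0% against 8.24% of other marked genes (Fisher's exact p = 7.76e-04, adjusted over 22 lists p = 0.0171). The other marked genes were not matched on CpG content, and such gaps lay at 13% of CpG-rich against 3.51% of CpG-poor marked genes. How much of the housekeeping excess went with CpG content was not tested. No other list passed after adjustment (adjusted exact p of 0.989 to 1). This does not show that they were alike, since the lists were too small for a shortfall to pass. Even 0 of 34 marked limb patterning transcription factors gave an unadjusted exact p of 0.111. On the lists other than housekeeping genes, uncovered 5′ ends between flanking peaks were found at Ckm, Hand1 and Hoxb7.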
